A study of Mus musculus with 14 samples.

How the data were processed

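Gene expression was measured by RNA sequencing in whole kidneys of male C57BL/6J mice. Per the labels' protocols, kidneys were snap frozen, total RNA was extracted with Qiagen's RNeasy Plus Midi kit and a column that removes genomic DNA, and libraries were made with Illumina's stranded TruSeq mRNA kit and sequenced in paired-end mode on a HiSeq4000. Per the submitters' processing notes, reads were aligned with STAR and counted with featureCounts on the mm10 genome build. Versions, gene annotation, strand setting and handling of reads that map to several genes are not given in the sources used here. The deposited table holds raw read counts per gene symbol, not normalised, with one column per library; the values are whole numbers whose totals differ between columns.

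Each library was assigned to its group from the labels, by treatment and time point. The 5 groups were vehicle control (3 libraries), Dps at 4 h (3), Dps at 24 h (3), MnDps at 4 h (3) and MnDps at 24 h (2). Both injected materials, called proteins in the text, were given at 18 mg/kg. Replicate numbers follow the order of the series, since the labels give none, and no library of the series was left out. The numbers in the library titles pass from DQ21, of MnDps at 4 h, to DQ23, of MnDps at 24 h. The labels do not explain this gap. Total counts per library ran from 15097093 to 42074942. Replicates of a group differed by more than counting error, with a chi-square per degree of freedom between 8.1 and 30.8 for pairs of libraries. The most abundant gene, Kap, took between 3.32% and 5.45% of the counts of a library.

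Genes with too few counts were removed with edgeR's filterByExpr by group, which kept 14854 of 24421 genes and removed 9567. Counts were scaled with the trimmed mean of M-values, and levels are CPM of the scaled library. The log2 fold changes come from edgeR (version 4.0.16 in R 4.3.3), with a robust dispersion estimate, and were tested with its quasi-likelihood F-test in one fit of 5 group means over all 14 libraries, which left 9 residual degrees of freedom. The SE of a log2 fold change is its size divided by the square root of F, a value reckoned from the test. P-values were adjusted by Benjamini and Hochberg's method within each comparison, and a gene was called at an adjusted p under 0.05. The biological coefficient of variation was 10.7%. The 9 comparisons were each treated group against control, MnDps against Dps at each time, 24 h against 4 h for each protein, and the interaction of protein and time. For a gene with no count in a group, the fold is given as a bound from 3 counts over that group.

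The comparisons, the test, the gene lists and the rule for naming genes were chosen before the data were examined. Of 36 gene lists, 34 had at least 5 tested genes and were tested with limma's camera (version 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera compares a list with all other genes; it was repeated with a correlation estimated from the data, and fry, which tests whether a list moves on balance in one direction and does not set it against other genes, was run beside it. By the naming rule, the text draws on the largest rises and falls with a mean of at least 1 CPM in the higher group and no overlap between the libraries compared (for the interaction without that condition), on called members of lists, and on Havcr1, Lcn2, Mt1, Mt2, Hmox1, Lrp2, Cubn and Slc34a1 in each comparison against control. These last 8 genes were printed elsewhere only where they belonged to such a list. Transcript length and GC content, taken from the longest transcript of each gene, were known for 14760 of the tested genes (99.4%).

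Alternatives chosen beforehand were median-of-ratios size factors, no count filter, a stricter one, DESeq2 (version 1.42.0), limma voom with library weights, a fit of only the groups compared, a minimum of 1.5-fold, the estimated correlation, fry, and leaving out each library in turn. Others were added after a principal component was seen to follow transcript length and after the totals were seen. In the length and GC correction, the spline trend of each library's log2 CPM on transcript length and GC content entered the fit as an offset; in the depth term, libraries of more than 30000000 counts received a term of their own. For comparisons that share controls, unchanged groups were simulated 20 times against the same simulated controls, and the real controls were split 1 and 2 in a fit of 6 group means, all 6 ways, which left 8 residual degrees of freedom; the split was chosen after the overlap had been seen. Where groups had 3 libraries each, all 10 splits of the 6 libraries were tested.

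The tests were checked on simulated counts for 14854 genes with the real means, spreads and library sizes, in which 200 genes were changed, 50 at each fold, and the 38 genes of the proximal tubule list were raised by 1.25-fold for the list test. For Dps at 4 h against control, 18% of genes changed by 1.25-fold were recovered, 68% at 1.5-fold, 88% at 2-fold and 100% at 4-fold, and 14 of 14616 unchanged genes were called. For MnDps at 24 h against control the shares were 6%, 40%, 84% and 98%, with 9 unchanged genes called. For MnDps against Dps at 24 h they were 10%, 58%, 84% and 98%, with 7. When a trend with transcript length was added, the length and GC correction took the unchanged genes called from 3072 to 8, from 2280 to 5 and from 2372 to 11 in these comparisons. Recovery of genes changed by at least 2-fold went from 91% to 92%, from 96% to 89% and from 98% to 92%. The added trend was of a form that the correction fits, so its removal was built in. No simulated change followed length, so the loss of real changes tied to length was not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 from tables read with pandas 2.3.3 and numpy 2.4.6.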

Results

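Messenger RNA was sequenced from the kidneys of male C57BL/6J mice that had received vehicle, Dps or MnDps. Both proteins were injected into a vein at 18 mg/kg, and kidneys were taken at 4 h or at 24 h. The series title presents the injected material as protein cages of nanometre size meant to reach the proximal tubule by passing the glomerular filter. The labels do not spell out either short name. They also do not say whether Dps and MnDps differ in their protein or only in something else about the cage. The 14 libraries form 5 groups, with 3 vehicle controls, 3 libraries each for Dps at 4 h, Dps at 24 h and MnDps at 4 h, and 2 for MnDps at 24 h. Total counts ran from 15097093 in replicate 1 of MnDps at 24 h to 42074942 in replicate 1 of Dps at 4 h. Replicates 1 and 2 of Dps at 4 h and replicate 3 of the controls exceeded 30000000 counts, and every other library held between 15097093 and 26490966. Of 24421 genes in the table, 14854 carried enough counts to be tested. Levels are normalised read counts (CPM) as mean ± SD, and log2 fold changes are given ± SE. The labels name no time point for the controls and do not say that libraries come from separate animals, so p-values measure the spread between these libraries.

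The first principal component, with 41.7% of the variance, separated all 6 libraries of the 4 h groups from the 8 others. The second component, with 20.6%, placed the controls and Dps at 4 h below 0 and the other 3 groups above it, and replicate 3 of MnDps at 4 h stood farthest out at 40.3. Across genes, which are not independent replicates, loadings on the second component fell with transcript length (Spearman's rho −0.62) and rose with GC content (rho 0.33).

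**Figure D1:**
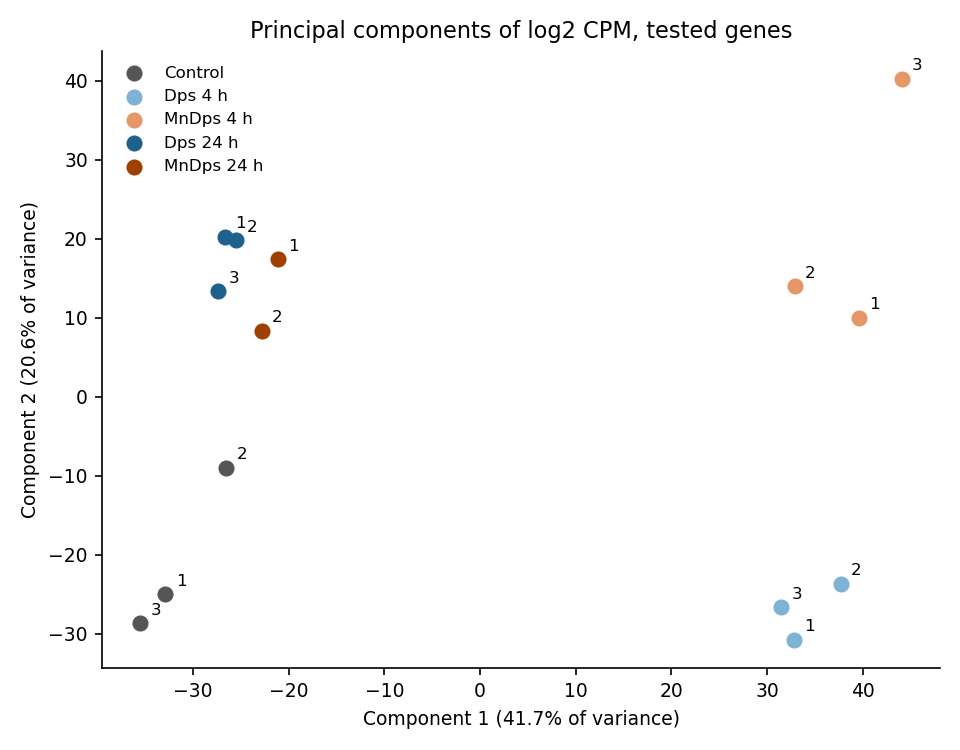
Principal components 1 and 2 of log2 CPM over the tested genes, one point per library, coloured by group and numbered by replicate. The 4 h libraries lie on the right, and replicate 3 of MnDps at 4 h lies highest on component 2 at 40.3.

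The comparison of Dps at 4 h with vehicle shows how kidneys differed from the controls early after the injection (n = 3 and 3). Endotoxin in the injected protein and an effect of the protein cannot be told apart in it. All 50 measured genes of the interferon response list rose, with a median log2 fold change of 3.79. Ifit1, an interferon-induced protein that binds foreign RNA, went from 5.83 ± 1.15 to 414 ± 71.8 CPM (log2 fold change 6.16 ± 0.17, adjusted p = 1.9e-12). Other members were Herc6 (3.73 ± 0.11), a ligase for the ubiquitin-like modifier Isg15, Parp14 (4.05 ± 0.14) and the RNA sensor gene Ddx58 (3.10 ± 0.11). Genes of acute inflammation rose with them: 30 of 38 members of the NF-kB list passed the test, and 34 when adjusted over the list alone. Among these were the monocyte attractant Ccl2 (4.55 ± 0.33), the macrophage growth factor Csf1 (2.51 ± 0.16), Nfkb2 (1.57 ± 0.11) and Steap4 (2.69 ± 0.21). Both lists passed camera and kept the call with an estimated correlation (adjusted p = 0.0004 and 0.013).

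Genes used as signs of tubule injury and of neutrophils also rose in this comparison, but the camera calls of both lists were lost with an estimated correlation (adjusted p = 0.278 and 0.18). The lists share members, so their counts are not separate evidence. Lcn2 is in the injury, NF-kB and neutrophil lists, among others, and Ccl2 and Vcam1 are in the injury and NF-kB lists. In the injury list, 15 of 28 genes rose (20 higher and 2 lower adjusted over the list alone), among them the protease inhibitor Timp1 (4.00 ± 0.32), the adhesion receptor Vcam1 (2.29 ± 0.26) and Cd44 (1.62 ± 0.24). Havcr1, the gene of kidney injury molecule 1, rose from 1.71 ± 0.53 to 4.01 ± 0.718 CPM (1.26 ± 0.35, adjusted p = 0.0248). Lcn2, which encodes the injury marker NGAL, rose from 3.57 ± 1.06 to 43.4 ± 13.4 CPM (3.66 ± 0.58, adjusted p = 0.00195). Of 8 neutrophil markers 6 rose, both over all genes and adjusted over the list alone, including the calgranulin genes S100a8 (5.17 ± 0.76) and S100a9 (5.12 ± 0.54). The stress genes Mt2, a metallothionein, and Hmox1, heme oxygenase 1, gave 1.37 ± 0.35, adjusted p = 0.0249 and 0.93 ± 0.23, adjusted p = 0.0204, and Mt1 0.27 ± 0.25, adjusted p = 0.518. The Mt2 call was lost without Dps 4 h replicate 2 (1.18) or control replicate 1 or 2 (1.27 each) and with a term for the deep libraries (1.27). The Hmox1 call was lost without Dps 4 h replicate 2 (0.92) or 3 (0.90) or control replicate 3 (0.97), and when these groups were fitted alone (0.94). Adipocyte markers rose in 8 of 14 genes (13 adjusted over the list alone), including Lep (4.36 ± 1.13) and Plin4 (2.04 ± 0.33), and the list lost its call with an estimated correlation (0.576). Their levels differed within the control group as well, with Adipoq at 0.0549 CPM in replicate 1 and 5.90 in replicate 2.

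Outside the interferon list, the largest rises by the fixed rule were those of Slfn4 (7.72 ± 0.23, adjusted p = 1.6e-12), the acute-phase gene Saa3 (6.79 ± 0.60), Olfr56 (6.25 ± 0.58) and Itih4 (5.96 ± 0.63). The longest GENCODE transcript of Olfr56 exceeds its RefSeq span, Ifit1 overlaps Ifit1bl1, and Ifit3 (5.69 ± 0.21) and Ifit3b (5.78 ± 0.17) are near-identical copies. The strand and multi-mapping settings of the counting are not given in the sources used here, so these values are uncertain. The largest falls were those of Cd209a (−4.17 ± 0.58, adjusted p = 7.5e-05), a lectin of dendritic cells, the matrix proteases Mmp12 (−3.44 ± 0.63) and Mmp13 (−2.82 ± 0.39), and Vipr1 (−2.44 ± 0.40). Endothelial markers fell on balance, with 8 of 20 lower and 3 higher (10 and 4 adjusted over the list alone). The list passed camera and lost the call with an estimated correlation (adjusted p = 0.723) and with fry (0.0523). Plvap, a component of endothelial diaphragms (−1.13 ± 0.16), and the angiopoietin receptor Tek (−1.10 ± 0.15) were among the genes that fell. Smaller falls were found for 7 of 37 respiratory chain genes (median −0.19; 13 adjusted over the list alone), 6 of 38 proximal tubule genes (median −0.15; 6) and 3 of 12 thick ascending limb markers (median −0.31; 6). Their calls too were lost with an estimated correlation (adjusted p = 0.723, 0.723 and 0.576). Lrp2 and Cubn, the megalin and cubilin receptors by which proximal tubule cells take up filtered protein, gave −0.23 ± 0.08, adjusted p = 0.0601 and 0.04 ± 0.08, adjusted p = 0.82. The phosphate transporter Slc34a1, whose gene overlaps Pfn3, did not pass (−0.15 ± 0.09, adjusted p = 0.26). The macrophage list moved both ways, with 4 genes higher, such as Itgam (1.86 ± 0.18) and Ly6c2 (2.41 ± 0.39), and 4 lower, such as the complement gene C1qa (−0.92 ± 0.16); its median was −0.13 and its mean 0.08.

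In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1237 genes were higher and 931 lower after Dps at 4 h, of which 531 and 139 changed by more than 2-fold. Without replicate 2 of Dps at 4 h the count of genes was 1435. The Havcr1 call was lost without Dps 4 h replicate 1 (log2 fold change 1.33) or 2 (1.12), or control replicate 1 (1.11) or 3 (1.19), and with the term for the deep libraries (1.23).

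**Figure D2:**
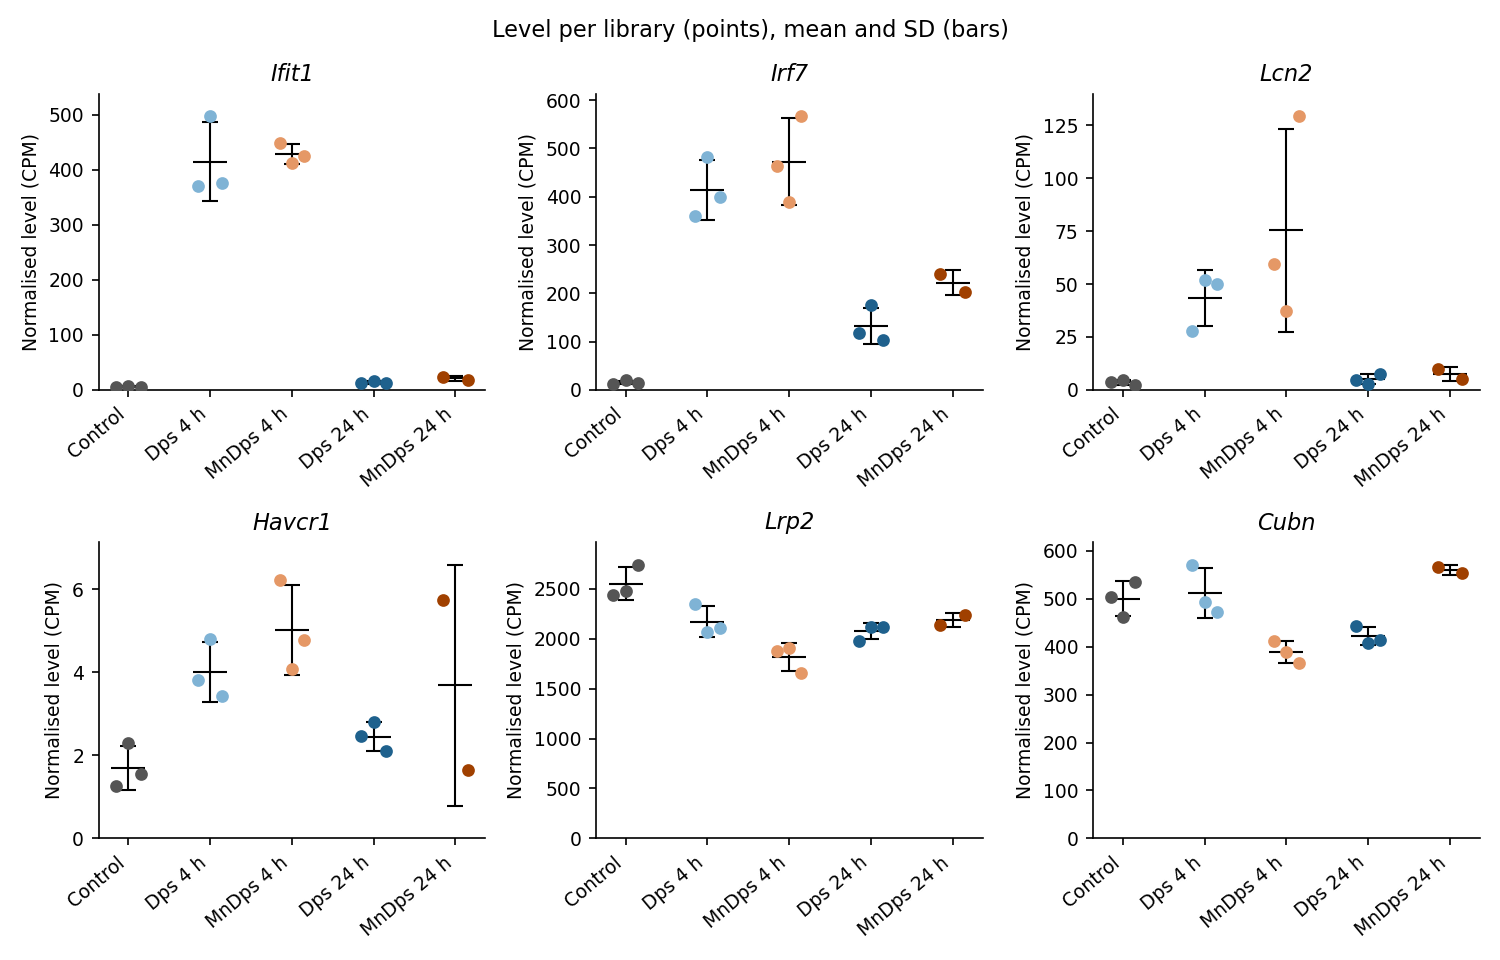
Normalised level in CPM of 6 genes in each library (points) by group, with the group mean and SD (bars); every vertical axis is linear and starts at 0. Ifit1 and Lcn2 stand high in both 4 h groups, Irf7 stays above the controls at 24 h, and Lrp2 and Cubn move by less than 2-fold.

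MnDps at 4 h was compared with vehicle in the same way (n = 3 and 3). The interferon response was again complete, with all 50 genes higher at a median of 3.83, and Ifit1 reached 428 ± 18.2 CPM (6.21 ± 0.17, adjusted p = 2.0e-12). This list kept its camera call with an estimated correlation (adjusted p = 0.00349), and the 11 other lists that passed camera in this comparison lost theirs. In the NF-kB list 33 of 38 genes rose and 1 fell (35 and 1 adjusted over the list alone; estimated-correlation adjusted p = 0.0983), and Saa3 had the largest rise by the fixed rule (7.71 ± 0.57, adjusted p = 4.8e-08). Tubule injury genes rose in 24 of 28 cases (25 adjusted over the list alone; median 1.12; estimated-correlation adjusted p = 0.211), including Timp1 (4.88 ± 0.32), Ccl2 (4.29 ± 0.33), Anxa1 (0.91 ± 0.13) and the cytokine receptor Tnfrsf12a (1.09 ± 0.13). Havcr1 reached 5.02 ± 1.09 CPM (1.57 ± 0.35, adjusted p = 0.00235) and Lcn2 75.3 ± 48.0 CPM (4.46 ± 0.58, adjusted p = 0.000245), with Lcn2 between 37.2 and 129 in the 3 libraries.

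Neutrophil markers rose in 6 of 8 genes (also 6 adjusted over the list alone), led by S100a8 (6.76 ± 0.68) and S100a9 (6.72 ± 0.50), but the call was lost with an estimated correlation (adjusted p = 0.193). Both metallothionein genes rose, Mt1 by 1.38 ± 0.25, adjusted p = 0.00127 and Mt2 by 2.35 ± 0.35, adjusted p = 0.000498, and so did Hmox1 (1.17 ± 0.23, adjusted p = 0.00193). The respiratory chain list had 24 of 37 genes higher and 1 lower (24 and 2 adjusted over the list alone; median 0.29), for example Ndufa2 (0.86 ± 0.13) and Cox4i1 (0.57 ± 0.09). That median was 0.01 once the trend of fold change with transcript length and GC content was removed, and the list no longer passed (adjusted p = 0.995; 0.71 with an estimated correlation). Lysosome and autophagy genes rose in 17 of 38 cases and fell in 2 (the same counts adjusted over the list alone), with progranulin Grn at 0.82 ± 0.09. Immediate early genes rose in 9 of 25 and fell in 1 (7 and 1 adjusted over the list alone), with Dusp2 at 2.36 ± 0.28. Both lists also lost their calls after the correction, each with adjusted p = 0.125, and with an estimated correlation (0.537 and 0.71). Adipocyte markers were higher in 6 of 14 genes (also 6 adjusted over the list alone), such as Fabp4 (1.03 ± 0.32), and lost the call with an estimated correlation (0.71).

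Several cell type markers of the kidney were lower after MnDps at 4 h. These list calls were lost with an estimated correlation, at an adjusted p of 0.537 for proximal tubule, 0.407 for endocytic receptor machinery, 0.537 for distal convoluted tubule and 0.588 for endothelial. Proximal tubule genes fell in 20 of 38 cases and rose in 3 (21 and 3 adjusted over the list alone), including the sodium-proton exchanger Slc9a3 (−1.86 ± 0.21) and the dicarboxylate transporter Slc13a3 (−0.53 ± 0.10). Endocytic receptor machinery fell in 13 of 27 genes and rose in 3 (the same adjusted over the list alone), among them the clathrin adaptor Dab2 (−0.59 ± 0.08); this call was lost after the length and GC correction (adjusted p = 0.0879). Lrp2 went from 2551 ± 164 to 1814 ± 139 CPM (−0.49 ± 0.08, adjusted p = 0.000182) and Cubn gave −0.36 ± 0.08, adjusted p = 0.00237, but with that correction the values were 0.00 and 0.14 and neither passed. Slc34a1 was lower (−0.38 ± 0.09, adjusted p = 0.00269; −0.36 with the correction). Distal convoluted tubule markers fell in 7 of 11 genes and rose in 1, for example Klhl3 (−1.20 ± 0.20). Endothelial markers fell in 12 of 20 and rose in 4, for example Ptprb (−1.74 ± 0.12) and Tek (−1.50 ± 0.16); the counts adjusted over each list alone were the same. The largest falls were those of Cd209a (−5.46 ± 0.74), Btnl9 (−3.83 ± 0.44), Trdn (−3.50 ± 0.48) and Ccdc85a (−3.37 ± 0.48).

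By the same test 3399 genes were higher and 3369 lower in MnDps at 4 h, with 655 and 501 beyond 2-fold, and 5609 passed with the length and GC correction.

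The changes after both proteins at 4 h were then set side by side. Of the genes higher after Dps, 909 were also higher after MnDps, where independent lists of these sizes would share 283, and 472 were lower in both, against 211. Log2 fold changes of the 2 comparisons correlated across genes at r = 0.77 with a covariance of 0.351. In 20 simulations of unchanged groups against the same 3 controls, r averaged 0.525 and the covariance 0.0313, and no gene was called in both. The simulations held no trend with transcript length, which ran opposite ways in the 2 comparisons (rho 0.17 after Dps and −0.47 after MnDps). After this overlap had been seen, the 3 controls were also split 1 and 2, so that each comparison had controls of its own, with a lone control assumed to vary like the other groups. Over the 6 ways to do so, 486 to 616 genes were higher in both and 117 to 242 lower, and r ran from 0.51 to 0.71. Independent lists would have shared 75.3 to 172 and 40.6 to 123, fewer than were shared in every one of the 6.

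At 24 h, Dps was compared with vehicle to see what was left of the changes seen at 4 h (n = 3 and 3). Of the interferon list, 10 of 50 genes rose and 1 fell (the same adjusted over the list alone), at a median of 0.27. The list passed camera, but not with an estimated correlation (adjusted p = 0.58) or with fry (0.137). With an estimated correlation the 9 other lists that passed camera here lost their calls too, at the same adjusted p. Irf7, a transcription factor that drives interferon production, remained above the controls at 133 ± 37.6 against 15.5 ± 3.80 CPM (3.11 ± 0.24, adjusted p = 6.8e-05). So did Bst2, the antiviral tetherin (2.36 ± 0.23, adjusted p = 0.000559), while Ifit1 was down to 13.6 ± 2.11 CPM (1.24 ± 0.17). Macrophage markers rose in 10 of 20 genes with none lower (11 higher adjusted over the list alone; median 0.75), including Aif1 (1.57 ± 0.27) and the Fc receptor chain Fcer1g (1.44 ± 0.20). Genes of fatty acid oxidation fell in 13 of 40 cases with none higher (17 adjusted over the list alone; median −0.30), among them Cpt1a, which admits fatty acids to mitochondria (−0.56 ± 0.09), and Cyp4a31 (−0.70 ± 0.13).

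Other lists passed camera in this comparison as well, and lost the call with an estimated correlation (adjusted p = 0.58 each). Respiratory chain genes were higher in 19 of 37 cases (30 higher and 1 lower adjusted over the list alone; median 0.28), but the median was −0.01 after the length and GC correction and the list no longer passed (adjusted p = 0.267). Cholesterol synthesis genes rose in 9 of 25 and fell in 1 (10 and 1 adjusted over the list alone), for example Fdps (0.82 ± 0.17), and lost the call with fry (0.0874). Principal cell markers of the collecting duct rose in 4 of 12 (5 adjusted over the list alone), for example the water channel Aqp2 (1.28 ± 0.23). Podocyte markers fell in 5 of 14 and rose in 1 (9 and 2 adjusted over the list alone). Distal convoluted tubule markers fell in 5 of 11 (also 5 adjusted over the list alone, with 1 higher), with Trpm6 at −0.83 ± 0.13. Adipocyte and urothelial lists passed with 2 of 14 and 1 of 11 genes called, and 2 and 0 adjusted over the list alone. Both lost the call with fry as well (0.0864 and 0.0874). The injury markers did not pass, with Havcr1 at 0.54 ± 0.38, adjusted p = 0.329 and Lcn2 at 0.59 ± 0.65, adjusted p = 0.557, nor did Mt1 (0.27), Mt2 (0.25), Hmox1 (−0.14) or Slc34a1 (−0.04). Lrp2 (−0.30 ± 0.08, adjusted p = 0.0164) and Cubn (−0.25 ± 0.08, adjusted p = 0.0471) were lower, but the correction gave 0.03 and 0.10. The Lrp2 call was also lost without Dps 24 h replicate 1 (−0.28) or control replicate 3 (−0.25), and the Cubn call without any one of these libraries but control replicate 2 (−0.29 to −0.19). Among the largest changes were rises of haptoglobin, Hp (2.97 ± 0.73), Serpina3n (2.76 ± 0.72) and Ccl5 (2.64 ± 0.45). The falls were led by Mmp13 (−3.63 ± 0.45), the proton pump gene Atp12a (−2.36 ± 0.52) and Irs2, an adaptor of insulin signalling (−2.31 ± 0.46).

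The quasi-likelihood test called 1432 genes higher and 1547 lower after Dps at 24 h, 112 and 126 of them by more than 2-fold. The count of genes was 1478 with the length and GC correction and 1637 with a term for the deep libraries. It was 843 without control replicate 3, 1194 without Dps 24 h replicate 2 and 1776 without Dps 24 h replicate 1.

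MnDps at 24 h was compared with vehicle on fewer libraries (n = 2 and 3). Of the interferon list, 26 of 50 genes were higher (30 higher and 1 lower adjusted over the list alone) at a median of 0.79. Interferon and the 11 other lists that passed camera here all lost their calls with an estimated correlation (adjusted p = 0.37 for interferon and for cell cycle and 0.414 for macrophage). Irf7 stood at 222 ± 26.3 CPM (3.85 ± 0.25, adjusted p = 1.7e-05), Bst2 rose by 2.85 ± 0.25, and Ifit1 was at 20.8 ± 3.71 CPM (1.83 ± 0.18). Cell cycle genes rose in 9 of 35 cases with none lower (the same adjusted over the list alone; median 0.44), among them the replication licensing genes Mcm3 (1.46 ± 0.19) and Mcm5 (1.49 ± 0.16) and cyclin E1, Ccne1 (1.90 ± 0.38). Macrophage markers rose in 9 of 20 (12 higher and 1 lower adjusted over the list alone; median 0.89), such as Aif1 (1.66 ± 0.30) and C1qa (1.05 ± 0.17).

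Markers of nephron segments moved in both directions after MnDps at 24 h. With an estimated correlation the adjusted p was 0.484 for each of proximal tubule, thick ascending limb and podocyte and 0.37 for principal cell, so these calls were lost. Proximal tubule genes fell in 5 of 38 (9 adjusted over the list alone), including Pck1, an enzyme of glucose synthesis (−0.99 ± 0.26). Thick ascending limb markers fell in 4 of 12 (also 4), including Umod (−0.64 ± 0.14) and Slc12a1 (−0.83 ± 0.17). Podocyte markers fell in 5 of 14 (7 lower and 1 higher), including Wt1 (−0.96 ± 0.17). Principal cell markers rose in 5 of 12 (6 adjusted over the list alone), with Aqp2 at 1.31 ± 0.25. The injury list passed with 1 gene higher, Vim (0.69 ± 0.15), and 1 lower, Sox4 (−0.62 ± 0.18), the same as adjusted over the list alone. It lost the call with an estimated correlation (adjusted p = 0.684) and with fry (0.208). The NF-kB list passed with 3 of 38 higher (also 3), among them complement C3 (2.06 ± 0.33), and lost the call in the same tests (0.684 and 0.208). Endothelial, urothelial and adipocyte lists passed with 2, 1 and 0 genes called, and 1, 1 and 0 adjusted over the list alone. They lost their calls with an estimated correlation (0.684, 0.605 and 0.684) and with fry (0.237, 0.104 and 0.237). With the length and GC correction, the injury (adjusted p = 0.166), NF-kB (0.074), endothelial (0.0501) and adipocyte (0.0501) calls were lost. The 8 marker genes reported against control in every case did not pass here: Havcr1 gave 1.07 ± 0.40, adjusted p = 0.0921, with 5.74 and 1.64 CPM in the 2 libraries, and Lcn2 1.10 ± 0.69, adjusted p = 0.317. Lrp2 gave −0.22 ± 0.09, adjusted p = 0.108 and Cubn 0.16 ± 0.09, adjusted p = 0.249, although Cubn did with the correction (0.41, adjusted p = 0.00601). Mt1 (0.63), Mt2 (0.64), Hmox1 (−0.03) and Slc34a1 (−0.18) did not pass either. The largest rises beside Irf7 were those of Ccr7 (3.56 ± 0.44), a homing receptor of lymphocytes and dendritic cells, Serpina3n (3.55 ± 0.72) and Apol7c (3.19 ± 0.41). The largest falls were those of Mmp13 (−3.15 ± 0.51) and Zim1 (−2.15 ± 0.62). The core clock gene Arntl also fell (−1.84 ± 0.32).

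Here 732 genes were higher and 1246 lower by the quasi-likelihood test, 144 and 66 of them by more than 2-fold. The gene count was 1012 with the length and GC correction and 1033 with the depth term. It was 300 without replicate 1 and 609 without replicate 2 of MnDps at 24 h, and 1221 and 779 without control replicates 1 and 3.

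Between both 24 h comparisons, 413 genes were higher and 567 lower in common, where independent lists would share 70.6 and 130. Their log2 fold changes correlated at r = 0.65 with a covariance of 0.125. In 20 simulations of unchanged groups the mean r was 0.421 and the covariance 0.0313, and no gene was called in both. The simulations held no trend with transcript length, while log2 fold change fell with length in both 24 h comparisons (rho −0.51 and −0.34). A split of the controls does not remove such a trend either. The overlap was not counted with the length and GC correction, so a shared trend and a shared response cannot be told apart. With the controls split in the same 6 ways, 6 to 105 genes were higher in both and 4 to 151 lower, and r ran from 0.28 to 0.46. Independent lists would have shared 0.438 to 19.2 and 0.595 to 51.1, again fewer in every one of the 6. The smallest counts came with control replicate 2 alone against Dps, where 6 genes were higher and 6 lower after Dps.

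The direct comparison of MnDps with Dps at 4 h asks what differed between these groups early on (n = 3 and 3). Respiratory chain genes were higher after MnDps in 33 of 37 cases (34 adjusted over the list alone; median 0.56), for example Ndufa1 (0.81 ± 0.08, adjusted p = 7.1e-05) and Cox4i1 (0.76 ± 0.09). After the length and GC correction the median was 0.15 (adjusted p = 0.000274). The call was lost with an estimated correlation (adjusted p = 0.947). Lysosome genes were higher in 20 of 38 cases and lower in 4 (23 and 4 adjusted over the list alone), such as cathepsin D, Ctsd (0.43 ± 0.07). NRF2 targets were higher in 13 of 27 with 1 lower (the same adjusted over the list alone), such as superoxide dismutase Sod1 (0.80 ± 0.10). The lysosome and NRF2 calls were lost with an estimated correlation (adjusted p = 0.947 each) and with the length and GC correction (0.0515 and 0.371). The interferon list did not pass, at a median of 0.03 with 5 genes higher and 5 lower. S100a8 (1.60 ± 0.37) and S100a9 (1.60 ± 0.28) were higher after MnDps, and so was Mt1 (1.11 ± 0.25, adjusted p = 0.00451; 0.59 with the correction, no longer past the test).

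Zfp366, a zinc finger protein of dendritic cells (−2.61 ± 0.40), Xylt1 (−2.32 ± 0.37) and Shroom4 (−2.45 ± 0.36), which overlaps another gene, were the largest falls. Erdr1 (1.69 ± 0.42), annotated as a transcribed pseudogene, and Scand1 (1.65 ± 0.26) were the largest rises. Cubn was lower (−0.40 ± 0.08, adjusted p = 0.00131) and Lrp2 as well (−0.26 ± 0.08, adjusted p = 0.0154), but the correction gave 0.11 and 0.23, and Lrp2 then passed as higher (adjusted p = 0.0106). Lrp2 did not pass without Dps 4 h replicate 1 (−0.21). Havcr1 and Lcn2 did not differ past the test (0.31 ± 0.32, adjusted p = 0.465, and 0.80 ± 0.46, adjusted p = 0.198). The test called 3085 genes higher and 3073 lower, with 100 and 292 beyond 2-fold. Genes higher after MnDps had a median transcript length of 1902 bases and genes lower of 5418, and log2 fold change fell with length across genes (rho −0.62). With the trend removed 3592 genes were called, 2675 of them called before in the same direction, and with the depth term 3558.

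**Figure D3:**
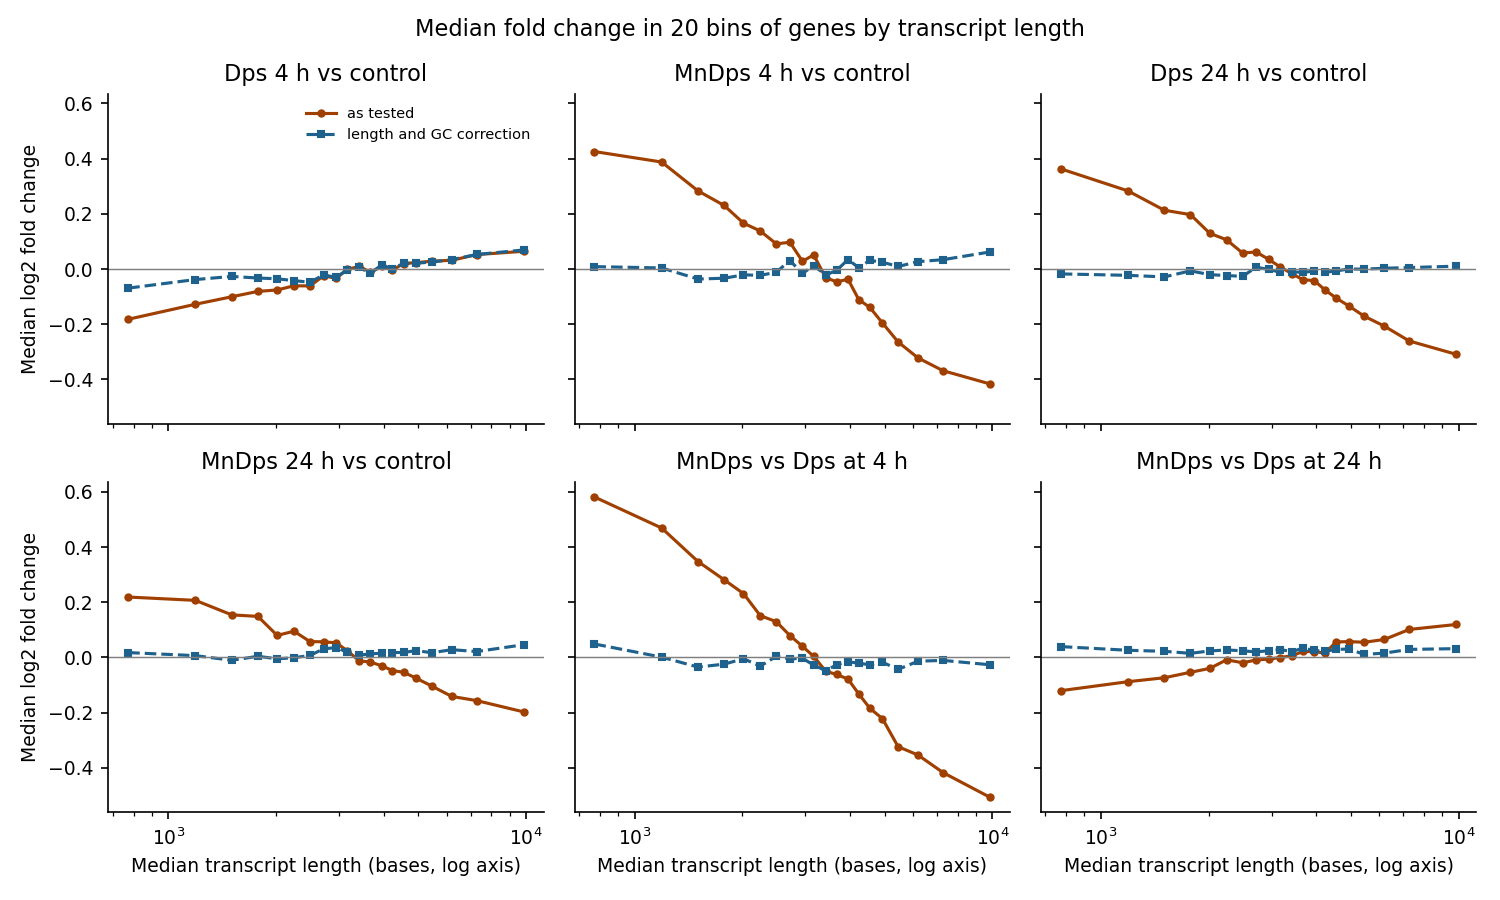
Median log2 fold change of tested genes in 20 bins of transcript length (log axis, bases) for 6 comparisons, as tested and after the length and GC correction. Between MnDps and Dps at 4 h the median ran from 0.58 in the shortest bin to −0.51 in the longest as tested, and from 0.05 to −0.03 after the correction.

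At 24 h the same contrast of MnDps with Dps gave few genes (n = 2 and 3). The interferon list was higher after MnDps at a median of 0.46, with 2 genes called over all genes, Irgm1 (1.03 ± 0.20, adjusted p = 0.0395) and Ddx58 (0.58 ± 0.12), and 14 adjusted over the list alone. It lost its camera call with an estimated correlation (adjusted p = 0.638) and with fry (0.223), and the 9 lists that follow lost theirs with an estimated correlation too. Cell cycle (median 0.44; 6 genes adjusted over the list alone), intercalated cell (0.26; 6), fatty acid oxidation (0.11; 8) and distal convoluted tubule lists (0.16; 1) were higher as well. The respiratory chain (median −0.21; 9 lower adjusted over the list alone), cholesterol synthesis (−0.21; 4), heat shock (−0.28; 2), glucocorticoid-responsive (−0.54; 1) and proximal tubule lists (−0.15; 2, with 1 higher) were lower. With an estimated correlation the adjusted p was 0.222 for intercalated cell, 0.361 for cell cycle, 0.687 for fatty acid oxidation, 0.759 for heat shock, 0.636 for cholesterol synthesis and 0.638 for each of the others. Intercalated cell kept its call with fry, and the others lost it: cell cycle (0.0566), respiratory chain and cholesterol synthesis (0.144 each), glucocorticoid, proximal tubule and distal convoluted tubule (0.257 each), fatty acid oxidation (0.319) and heat shock (0.393). Over all genes these 9 lists had 0, 1, 2 and 1 genes higher and 0, 0, 1, 1 and 1 lower, in that order, plus Cubn higher (0.41 ± 0.09, adjusted p = 0.0491; 0.30 with the correction, not past the test). The Cubn call was lost without any one of the 5 libraries compared (0.38 to 0.44).

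Among genes past the test, Cyp4a12b (1.35 ± 0.24), a near-identical copy of Cyp4a12a whose value is uncertain for that reason, Kcnip2 (1.08 ± 0.24) and Acot3, a peroxisomal thioesterase (0.84 ± 0.15), were higher after MnDps. Gt(ROSA)26Sor, which overlaps Thumpd3 (−2.01 ± 0.22), Zxda (−1.21 ± 0.21) and Calcrl, a receptor of calcitonin-family peptides (−1.04 ± 0.16), were lower. In all, 22 genes were higher and 99 lower, 2418 genes had an unadjusted p under 0.05, DESeq2 called 563 and limma voom 716, and the count was 727 with these groups fitted alone and 68 with the depth term. Leaving out a library gave 5 genes without MnDps replicate 1, 22 without its replicate 2, and 45, 16 and 15 without Dps replicates 1, 2 and 3.

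Dps at 24 h was next compared with Dps at 4 h (n = 3 and 3). The controls have no time point, so time since injection and hour of collection cannot be told apart here. All 50 interferon genes were lower at 24 h, at a median of −3.73. With an estimated correlation the interferon call held (adjusted p = 0.00487), and it was lost for NF-kB (0.0929) and for injury, neutrophil, fatty acid oxidation, endothelial and macrophage lists (0.691 each). Also lower were 33 of 38 NF-kB genes (34 adjusted over the list alone; median −1.60), for example Ccl2 (−4.52 ± 0.33, adjusted p = 5.3e-08). Injury genes were lower in 13 of 28 and higher in 2 (the same adjusted over the list alone), with Timp1 at −3.32 ± 0.30. Neutrophil markers were lower in 6 of 8 (also 6), with Lcn2 at −3.07 ± 0.55, adjusted p = 0.00143. Fatty acid oxidation genes were lower in 21 of 40 and higher in 2 (22 and 3 adjusted over the list alone), among them Vnn1 (−0.99 ± 0.10). Endothelial markers were higher in 10 of 20 and lower in 3 (the same adjusted over the list alone), with Plvap at 1.51 ± 0.16. Macrophage markers were higher in 10 of 20 and lower in 3 (11 and 3), with C1qa at 1.93 ± 0.16.

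Respiratory chain genes were higher in 34 of 37 cases (also 34 adjusted over the list alone), at a median of 0.50 that was 0.14 after the correction (adjusted p = 0.000374). Principal cell markers were higher in 6 of 12, NRF2 targets in 12 of 27 with 2 lower, and cholesterol synthesis genes in 11 of 25 with 1 lower, the same as adjusted over the list alone. All 4 of these calls were lost with an estimated correlation (adjusted p = 0.666 for respiratory chain and principal cell and 0.691 for the others), and the principal cell (0.0652) and NRF2 calls (0.128) were lost with the correction. Slfn4 (−5.91 ± 0.20), Oasl1 (−5.70 ± 0.25) and Serpina3f (−5.45 ± 0.41) were among the largest falls. Cd209a (3.73 ± 0.60), Vipr1 (2.87 ± 0.39) and Gadd45g, a stress-induced growth regulator (2.50 ± 0.35) were among the largest rises. Mt2 (−1.12 ± 0.34, adjusted p = 0.0231) and Hmox1 (−1.07 ± 0.24, adjusted p = 0.0033) were lower at 24 h, but the Mt2 call was lost without Dps 4 h replicate 2 (−0.93) or Dps 24 h replicate 1 (−1.04) or 3 (−1.11). Havcr1 gave −0.72 ± 0.34, adjusted p = 0.0964, and Cubn was lower as tested (−0.28 ± 0.08) and at 0.07 after the correction, and its call was lost without Dps 4 h replicate 1 (−0.21) or Dps 24 h replicate 2 (−0.26). The test called 3270 genes higher and 3356 lower, and 4225 with the depth term.

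MnDps at 24 h was compared with MnDps at 4 h in the same way and with the same limit (n = 2 and 3). All 50 interferon genes were lower at 24 h (median −3.07), as were 26 of 38 NF-kB genes (29 adjusted over the list alone). Also lower were 16 of 28 injury genes (19) and 6 of 8 neutrophil markers (also 6), with S100a8 at −5.98 ± 0.77, adjusted p = 5.7e-05 and Lcn2 at −3.36 ± 0.63, adjusted p = 0.00498. With an estimated correlation the interferon call held (adjusted p = 0.00282), while NF-kB (0.0753), injury and neutrophil (0.171 each) lost theirs. The cell cycle inhibitor Cdkn1a (−1.69 ± 0.23) and Fas (−1.31 ± 0.21) fell among 9 of 23 p53 targets. Atf3 (−1.90 ± 0.40) and Maff (−2.14 ± 0.36) fell among 9 of 25 immediate early genes (the same counts adjusted over the list alone). The p53 (0.171) and immediate early (0.397) calls were lost with an estimated correlation, and so were endothelial (0.171), macrophage (0.333) and clock (0.319). Endothelial markers were higher in 14 of 20 (15 higher and 2 lower adjusted over the list alone), with Tek at 1.78 ± 0.17. Macrophage markers were higher in 10 of 20 and lower in 1 (12 and 2), with Cx3cr1 at 2.12 ± 0.25. Clock genes were higher in 8 of 23 and lower in 2 (11 and 4), with Arntl at −2.17 ± 0.32.

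Higher lists also included intercalated cell (7 of 14 genes; 9 adjusted over the list alone), with the anion exchanger Slc4a1 at 1.33 ± 0.24, and matrix (12 of 27, 4 lower; 12 and 5), with Mmp2 at 1.63 ± 0.31. Cell cycle (8 of 35, 1 lower; the same), stromal (5 of 15; 6), distal convoluted tubule (4 of 11; 4) and principal cell lists (3 of 12; 4) were higher too. All 6 of these calls were lost with an estimated correlation, at an adjusted p of 0.169 for intercalated cell, 0.664 for matrix, 0.397 for cell cycle, 0.171 for stromal, 0.397 for distal convoluted tubule and 0.262 for principal cell, and matrix also lost its call with fry (0.154). Lower lists also included respiratory chain (16 of 37; 19 adjusted over the list alone), fatty acid oxidation (13 of 40; 14), with Acot1 at −1.51 ± 0.19, and glucocorticoid-responsive genes (10 of 25, 1 higher; 12 and 1), with Pck1 at −1.69 ± 0.26. These 3 calls were lost with an estimated correlation (0.552, 0.397 and 0.664), and the glucocorticoid call with fry as well (0.117). With the length and GC correction the respiratory chain (adjusted p = 0.182) and matrix (0.277) calls were lost. Olfr56, which had no count in MnDps at 24 h, was at least 4.67 log2 units lower, reckoned from 3 counts over that group. Cxcl10, which overlaps Art3, was lower by the test (−4.80 ± 0.36). Btnl9 (3.67 ± 0.47), Hhip, a binder of hedgehog ligands (3.33 ± 0.78), and Astn1 (2.87 ± 0.57) rose most. Mt2 (−1.70 ± 0.40, adjusted p = 0.0134) and Hmox1 (−1.20 ± 0.27, adjusted p = 0.00906) were lower at 24 h, and Cubn was higher (0.52 ± 0.09, adjusted p = 0.000861; 0.26 with the correction).

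In this comparison 1502 genes were higher and 1740 lower, and the count was 1837 without replicate 1 and 1336 without replicate 2 of MnDps at 24 h, and 1878 when these groups were fitted alone. Without replicate 2 of MnDps at 24 h the calls of Lcn2 (−2.95), Mt2 (−1.45) and Hmox1 (−1.12) were lost, and that of Mt2 also when these groups were fitted alone (−1.69).

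The interaction asks whether the difference between MnDps and Dps at 24 h departs from that at 4 h. The 3 lists that passed camera lost the call with an estimated correlation (adjusted p = 0.864 each), and interferon and heat shock also with fry (0.201 each). Respiratory chain genes had a lower difference at 24 h in 34 of 37 cases (35 adjusted over the list alone; median −0.76, and −0.21 with the length and GC correction), for example Cox7a2 (−1.06 ± 0.14, adjusted p = 0.000361). Interferon genes had a higher one in 13 of 50 (12 adjusted over the list alone; median 0.49), for example Ifit2 (1.17 ± 0.24). Heat shock genes had a lower one in 5 of 25 (4; median −0.40), for example the chaperonin gene Hspe1 (−1.28 ± 0.15). The difference was higher for 2034 genes and lower for 2334, and the total was 2104 with the length and GC correction and 2724 without replicate 2 of MnDps at 24 h.

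**Figure D4:**
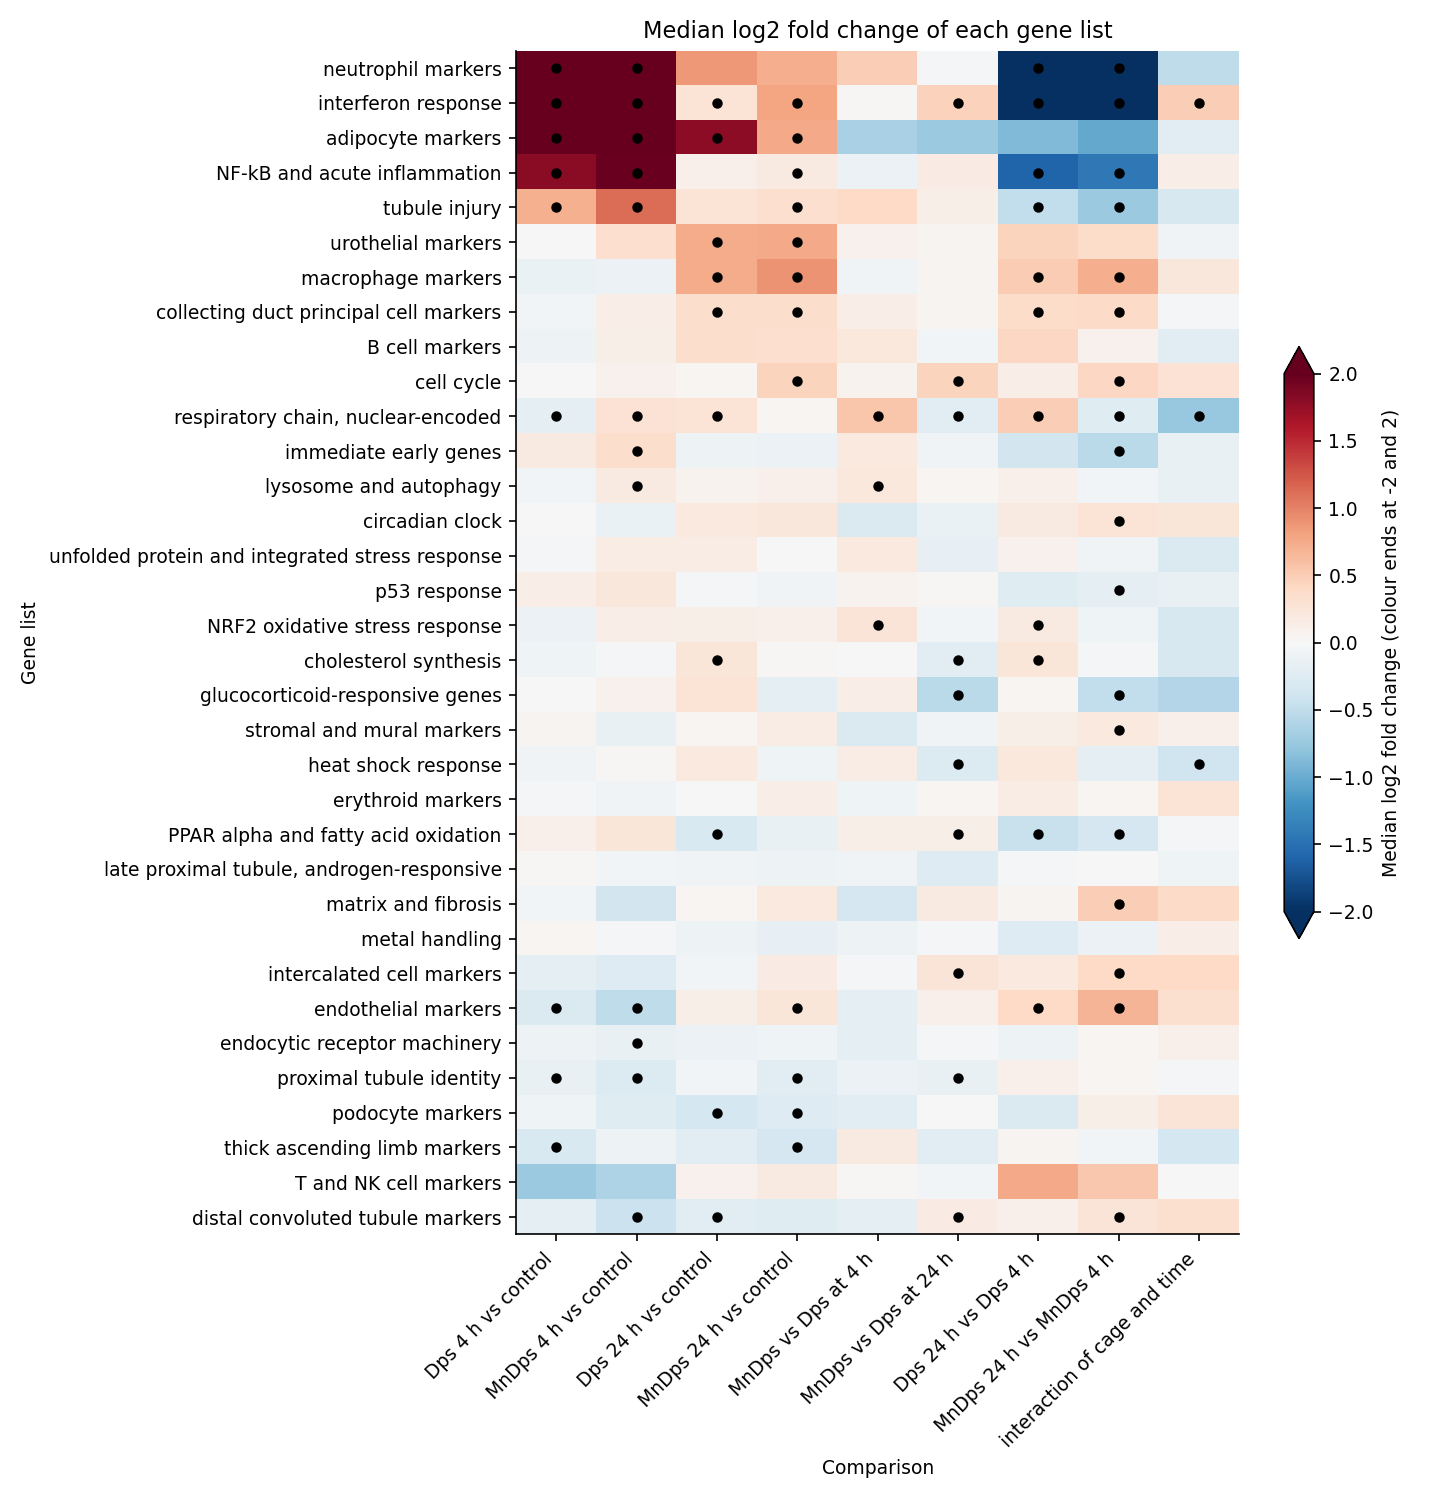
Median log2 fold change (colour, ending at −2 and 2) of the 34 tested gene lists (vertical axis) in the 9 comparisons (horizontal axis); a dot marks a list past camera at an adjusted p under 0.05. The interferon list passes in 8 comparisons, at a median of 3.79 after Dps and 3.83 after MnDps at 4 h, and loses the call with an estimated correlation in 4 of the 8, which are both 24 h comparisons with control, MnDps against Dps at 24 h, and the interaction.

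Of the 34 lists, 6 passed camera in none of the 9 comparisons. Their lowest adjusted p was 0.073 for metal handling, 0.1 for the unfolded protein and integrated stress response, 0.101 for late proximal tubule transporters that respond to androgen, 0.108 for T and NK cell markers, 0.4 for B cell markers and 0.491 for erythroid markers. Camera asks for a net direction, so a list whose genes move both ways can miss it. Of metal handling genes, up to 17 of 29 were called in a comparison. The copper protein gene Cp, for example, rose after MnDps at 4 h (1.27 ± 0.19). Of stress response genes, up to 15 of 30 were called, and Trib3 rose after Dps (1.90 ± 0.26) and MnDps at 4 h (2.08 ± 0.26). Among all tested genes the share called reached 45.6%, for MnDps at 4 h against control. Of the adrenal markers 2 genes were tested, with 1 higher after MnDps at 4 h than in control and than after Dps and none called elsewhere, and the table held no mitochondrially encoded transcript. In the GRCm38.p6 annotation (the mm10 build), Ifit1 lies on chromosome 19, 34640889 to 34650009, Irf7 on chromosome 7, 141263183 to 141266499 and Lcn2 on chromosome 2, 32384637 to 32387739. Havcr1 lies on chromosome 11, 46739822 to 46779578, Lrp2 on chromosome 2, 69424335 to 69586029 and Cubn on chromosome 2, 13276338 to 13491876; all are protein-coding genes. Other genes named here whose span overlaps that of another gene, so that their values are uncertain in the same way, are Astn1, C3, Cox7a2, Cp, Hspe1, Irs2, Klhl3, Ndufa1, Ndufa2, Nfkb2, Plin4, Plvap, Scand1, Timp1, Tnfrsf12a and Trdn.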

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

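The length and GC correction and the depth term, as tests of explanations for the difference between MnDps and Dps, were chosen after that result had been seen. Leaving out each library, the interaction and the splits of the libraries were chosen before, but weighing replicate 3 of MnDps at 4 h as a cause was chosen after.

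The difference between MnDps and Dps was not the same at 24 h as at 4 h for 4368 genes by the test of the interaction. Its log2 fold change rose with transcript length across genes (rho 0.59). With the length and GC correction 2104 genes passed, 1599 of them called before in the same direction. Tested on gene lists without the correction, the interaction passed for interferon response (median 0.49), heat shock (median −0.40) and respiratory chain genes (median −0.76). Each of these lists lost the camera call with an estimated correlation (adjusted p = 0.864). With fry, interferon and heat shock lost it (0.201 each) and respiratory chain kept it (0.0022). Among genes picked by the fixed rule, the difference was higher at 24 h for Itga2 (3.88 ± 1.13), Shroom4 (3.48 ± 0.54), Zbed6 (3.34 ± 0.66), Zfp366 (3.24 ± 0.58) and Hhip (3.06 ± 0.99). It was lower for Gadd45g (−2.34 ± 0.52), Eva1c (−2.25 ± 0.52), Erdr1 (−1.97 ± 0.62), Cebpd (−1.87 ± 0.48) and Cebpb (−1.79 ± 0.36). With the length and GC correction Itga2 (adjusted p = 0.0651), Hhip (0.113) and Erdr1 (0.352) no longer passed. Shroom4, Zbed6 and Cebpd overlap other genes, so their values are uncertain.

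More genes differed between MnDps and Dps at 4 h (6158, 3 libraries with 3) than at 24 h (121, 2 with 3, and 5 to 727 over the alternatives), and a trend of fold change with transcript length and GC content, replicate 3 of MnDps at 4 h, and unequal depth were weighed as whole causes of the 4 h count. With the trend removed 3592 genes differed, without that replicate 4670, and with the depth term 3558, where 5% of the tested genes, 742.7, was the bound below which each would have been kept as the whole cause. That bound was set after the count had been seen. Each explanation was taken alone and no fit combined them, so these counts cannot show whether they account for the 4 h count together. Respiratory chain genes differed in the 2 comparisons of MnDps at 4 h. Against control the median fell from 0.29 to 0.0136 with the trend removed (camera adjusted p = 0.995), so that trend may account for this rise. Against Dps a median of 0.151 was left of 0.56 (camera adjusted p = 0.000274 at the preset correlation, SE of the median 0.0482). That SE takes the 37 genes as independent. With an estimated correlation the list did not pass even before the correction (camera adjusted p = 0.947), and that test was not run after it. Whether the trend accounts for all of this rise therefore stays open. The trend may still add to the 3592 genes' folds, and what made libraries differ in it was not tested. An effect of the MnDps cage stays open and was not tested apart from these, since each group is one treatment at one time.

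Other splits of the 6 libraries in a comparison were counted for the 5 comparisons of 3 with 3. There are 10 such splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes in each comparison. The real split gave 1891 genes for Dps at 4 h against control, 5276 for MnDps at 4 h against control, 3057 for Dps at 24 h against control, 5543 for MnDps against Dps at 4 h and 7195 for Dps at 24 h against 4 h, and the highest other split gave 0 in each. Every other split puts libraries of both groups on each side, so few calls were to be looked for there, and the counts of 0 decide nothing. All these counts come from fits of the 6 libraries alone.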

How the results depend on the processing

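The length and GC correction and the depth term were chosen after the data had been seen, and the other alternatives before.

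Counts of called genes moved by more than 1.5 times as follows, and the cause was not tested except that a minimum fold keeps fewer genes by construction. With a minimum of 1.5-fold they were 1141 (Dps 4 h against control), 2811 (MnDps 4 h), 764 (Dps 24 h), 759 (MnDps 24 h), 2084 (MnDps against Dps at 4 h), 58 (at 24 h), 2785 (24 h against 4 h for Dps), 1557 (for MnDps) and 2673 (interaction). With the length and GC correction they were 1478 for Dps and 1012 for MnDps at 24 h, 3592 for MnDps against Dps at 4 h and 2104 for the interaction. With the depth term they were 1637 and 1033 for the same 24 h comparisons, 3558 and 68 for MnDps against Dps at 4 h and 24 h, and 4225 for Dps at 24 h against 4 h. For MnDps against Dps at 24 h, DESeq2 gave 563, limma voom 716 and a fit of these groups alone 727; for MnDps at 24 h against 4 h the last gave 1878. Size factors and both count filters moved none by that much.

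Leaving out 1 library at a time gave 1435 to 1849 genes for Dps at 4 h, 4956 to 6814 for MnDps at 4 h, 843 to 3529 for Dps at 24 h and 300 to 2562 for MnDps at 24 h, each against control. It gave 4670 to 5948 for MnDps against Dps at 4 h, 5 to 45 at 24 h, 5203 to 5918 for Dps at 24 h against 4 h, 1336 to 3176 for MnDps and 2724 to 4598 for the interaction. The lowest counts came without Dps 4 h replicate 2, control 3 (MnDps 4 h and Dps 24 h), MnDps 24 h replicate 1 (both its 24 h comparisons), MnDps 4 h replicate 3, Dps 24 h replicate 2 and MnDps 24 h replicate 2 (the last pair). A lone MnDps 24 h library is assumed to vary like the other groups. No paired analysis was possible, as the labels give no replicate numbers.

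Of 88 list results past camera, all kept their call with size factors and with no count filter, 85 in fits of only the groups compared, 73 with the length and GC correction, 65 with fry and 5 with an estimated correlation. With a library left out, 461 list tests kept the call, 42 lost it and none changed direction. Over 967 results of named genes and 13705 alternatives, 12454 kept direction and side of the threshold, 1204 no longer passed, 9 newly passed and 38 changed direction.

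Fits of only the groups compared lost lysosome for MnDps at 4 h (adjusted p = 0.0659), adipocyte for MnDps at 24 h (0.115) and cholesterol for Dps over time (0.0864). Calls lost with a library left out follow. Against control, Dps at 4 h lost proximal tubule without Dps replicates 2 (0.0864) or 3 (0.0835) or control 3 (0.0618), and endothelial without Dps 1 (0.116). MnDps at 4 h lost immediate early without MnDps 3 (0.0722) or control 1 (0.13), and lysosome and distal convoluted tubule without control 1 (0.0556 each). MnDps at 24 h lost podocyte (0.114), proximal tubule (0.0672), adipocyte (0.485), injury (0.184) and endothelial (0.0686) without MnDps 1. It also lost adipocyte without control 1 (0.162) or 3 (0.0658), injury without control 3 (0.0914), endothelial without control 2 (0.195), and NF-kB without control 2 (0.0504) or 3 (0.0861). MnDps against Dps lost NRF2 at 4 h without Dps 2 (0.075). At 24 h it lost fatty acid oxidation, proximal tubule and distal convoluted tubule without MnDps 1 (0.481 each), the last also without Dps 1 (0.154), and glucocorticoid without MnDps 2 (0.119). Dps over time lost NRF2 and neutrophil without 4 h replicate 2 (0.0881 each), NRF2 and cholesterol without 24 h replicate 2 (0.0534 and 0.0871), and cholesterol without 4 h replicate 3 (0.116). MnDps over time lost cell cycle and distal convoluted tubule without 24 h replicate 1 (0.13 each), and the latter without 4 h replicate 3 (0.0598). It lost glucocorticoid without 4 h replicate 3 (0.0812) or 24 h replicate 2 (0.49), and matrix without 4 h replicates 1 (0.0662) or 2 (0.0817) or 24 h replicate 1 (0.143). The interaction lost heat shock and interferon without Dps 4 h replicate 2 (0.0714 and 0.0595), heat shock without Dps 24 h replicate 3 (0.0859) and interferon without MnDps 24 h replicate 1 (0.09).

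Genes outside the naming rule, such as Clock after MnDps at 4 h against control, were not counted here. Among the 967 results of named genes, the length and GC correction changed 27 directions. They were Cubn (0.14), Fech (0.0063) and Lrp2 (0.00057) for MnDps at 4 h; Cubn (0.10), Lrp2 (0.026), Mt1 (−0.064), Mt2 (−0.24) and Ppp1r1a (−0.034) for Dps at 24 h. For MnDps against Dps at 4 h they were Apela (−0.055), Clock (0.11), Cubn (0.11), Emx1 (−0.20), Fech (0.047), Igfbp7 (−0.12; it overlaps Polr2b), Lrp2 (0.23), Myh11 (0.011), Pcna (−0.063) and Slc25a37 (0.0084). The others were Cubn (0.070), Emx1 (−0.22), Fech (0.042) and Kap (−0.073) for Dps over time; Lrp2 (−0.043) for MnDps over time; and Ftl1 (0.21), Igfbp7 (0.048), Lrp2 (−0.30) and Pcna (0.072) for the interaction. Other changes were in genes not called. Cubn after Dps at 4 h was −0.018 with the depth term, −0.033 without Dps 1 and −0.031 without control 2. Hmox1 at 24 h was 0.046 without Dps 1 and 0.090 without control 2 for Dps, and lowest (−0.40) without control 1. For MnDps it was 0.0050 with limma voom, 0.055 without MnDps 2, 0.20 without control 2 and 0.0095 without control 3, and lowest (−0.29) without control 1. Slc34a1 after Dps at 24 h was 0.0039 without Dps 3 and lowest at −0.11 without replicate 2. Havcr1 after MnDps at 24 h was −0.044 without MnDps 1, and 1.76 and past the test without replicate 2. Their cause was not tested.

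After Dps at 4 h, Mt2 did not pass without Dps 2 (1.18) or control 1 (1.27) or 2 (1.27), nor with the depth term (1.27), and Hmox1 not without Dps 2 (0.92) or 3 (0.90) or control 3 (0.97), nor fitted alone (0.94). Lrp2 did not pass as reported (−0.23) but did with the length and GC correction, the depth term, DESeq2, limma voom and the stricter filter (−0.27 to −0.23). At these library sizes and spreads, 18% of the smallest changes were recovered in the simulation of Dps at 4 h.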

Other observations

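The tests of leukocytes, endotoxin and the hour of collection as explanations were chosen after the results they address had been seen; the gene tests and the list tests were chosen before, and the length and GC correction after.

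Interferon response genes rose in both 4 h groups, with a summed level of 722 CPM in control, 11939 after Dps and 12261 after MnDps. Leukocytes that entered the kidney were weighed as the main source of this rise. The weighing used 4 genes taken as leukocyte markers, Ptprc, Coro1a, Laptm5 and Tyrobp, of which Tyrobp is also in the macrophage list. Their median log2 fold change was −0.303 after Dps (SD 0.389) and −0.327 after MnDps (SD 0.613), against 3.79 and 3.83 for the interferon list, and their summed level went from 39.6 CPM to 33.0 and 34.5, which argues against a net gain of leukocytes as the main source of the rise. These 4 genes cannot show whether one kind of leukocyte took the place of another. A smaller share from leukocytes such as neutrophils stays open, since 6 of 8 neutrophil markers rose in each 4 h group and, of these 4 genes, Coro1a was called higher after MnDps (0.63 ± 0.13, adjusted p = 0.000939), although Ptprc (−0.82 ± 0.19, adjusted p = 0.00265) and Laptm5 (−0.42 ± 0.14, adjusted p = 0.0242) were called lower, as was Laptm5 after Dps (−0.70 ± 0.14, adjusted p = 0.0029). With the length and GC correction the Ptprc call after MnDps was lost (−0.36, adjusted p = 0.102), and Tyrobp passed there as lower (−0.71, adjusted p = 0.00325). Coro1a and Laptm5 kept their calls after MnDps. Endotoxin in the injected protein and an effect of the cages cannot be told apart, because 0 groups received anything but vehicle without a cage, and a change of state in cells already in the kidney was not tested.

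At 24 h the same genes were higher than in control in both groups, except Ptprc, which was not called (0.19 ± 0.18 after Dps and −0.05 ± 0.21 after MnDps). Coro1a gave 1.35 ± 0.13 and 1.35 ± 0.14, Laptm5 0.76 ± 0.14 and 0.75 ± 0.15, and Tyrobp 0.90 ± 0.18 and 0.98 ± 0.19, with an adjusted p between 4.1e-05 and 0.00653. With the length and GC correction Tyrobp no longer passed after Dps (0.0748). The values at 4 h therefore do not speak against leukocytes for interferon genes that were higher at 24 h.

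Clock genes were called in both 24 h groups against control, but the clock list of 23 genes, fixed beforehand, did not pass camera there (adjusted p = 0.1 for Dps and 0.108 for MnDps), while with the length and GC correction it passed for Dps (0.00562) and not for MnDps (0.0501). Arntl was at 5.46 CPM in control, 1.76 after Dps and 1.47 after MnDps at 24 h, and Dbp at 117, 187 and 244; Dbp, Per3 and Ciart overlap other genes, so their values are uncertain. A set of 9 clock genes, picked after their values had been seen so that the tally decides nothing, held 3 of the positive limb (Arntl, Clock, Npas2), lower, and 6 that limb drives (Dbp, Tef, Per1, Per2, Per3, Ciart), higher, in both 24 h groups, with 6 called after Dps and 5 after MnDps. With the correction Clock at 24 h went from −0.47 ± 0.10 to −0.11 after Dps (adjusted p = 0.349) and from −0.74 ± 0.11 to −0.35 after MnDps, and Tef no longer passed after MnDps at 24 h (0.0537). At 4 h without the correction, 4 and 2 of the 9 moved that way, with 0 called after Dps. After MnDps at 4 h, 1 was called that way (Clock) and 3 the opposite way. With the correction that Clock call was lost and its direction turned (0.10, adjusted p = 0.307). The opposite call of Per3 was lost too (−0.10, adjusted p = 0.365). Those of Tef (−0.31, adjusted p = 0.0138) and Ciart (−1.19, adjusted p = 0.0111) were kept. Between 24 h and 4 h of each protein, all 9 genes moved as they did at 24 h against control, with 7 called for each protein. The hour at which kidneys were taken and an effect of the proteins cannot be told apart, because 0 controls have a time point. This holds for the comparisons of 24 h with 4 h and of 4 h with control too.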
